A study of Mus musculus with 4 samples.

How the data were processed

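The series measured RNA from primary colonic epithelial cells of C57BL/6 mice, with 2 wild-type (WT) libraries and 2 Mettl14 knockout (KO) libraries. Per the labels' protocols, mRNA was selected from total RNA with oligo-dT beads, fragmented, copied to cDNA, ligated to adapters, amplified by PCR and sequenced on an Illumina instrument. The submitters' processing notes name FastQC 0.11.2, STAR 2.4.2a, RSEM 1.2.29 and the genome build mm10, without saying which step each tool served. The deposited values are whole-number counts per gene that the authors did not normalise, judged from the values, which sum to a different total in each library. Whether they are rounded estimates, the annotation release and the strandedness of the counting are not given in the sources used here. Reads shared between near-identical genes, overlapping genes or antisense partners may therefore have been assigned in more than one way.

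The table held 50600 genes, and 0 of its columns were left without a sample. Gene identifiers were matched to GENCODE release M21 (GRCm38, the assembly of mm10), which held 99.56% of them. The remaining identifiers carried 0.0102% of the counts. Coordinates are from that annotation and are 1-based. Groups were taken from the genotype label, and replicates were numbered in accession order, so the numbers pair no libraries. The sample titles all share a further code that was not used, and whether it stands for an age or a time is not stated. Sex was read from Xist and 4 Y-linked genes. It differed within both groups, with 1 male and 1 female library in each, so the libraries of a group came from different animals. The labels do not say so themselves, nor whether a library pooled several animals, and p-values measure only the spread between these samples.

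Library totals ran from 22136440 to 24991060 counts. A count of 0 allows a level of up to 3 counts, or 0.12 to 0.136 CPM (counts scaled to the library total). These limits cover counting error only. Genes were kept with filterByExpr, which left 14861, and scaled with trimmed mean of M-values (TMM) factors. The test was edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3, legacy and robust options on), KO against WT, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design leaves 2 residual degrees of freedom. CPM are given as mean ± SD (n = 2) after TMM scaling, and log2 CPM used an offset of 0.5.

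Gene lists, 39 in all, were fixed before the data were examined. All of their entries were found in the table, 4 of them through the gene identifier. For lists with at least 5 tested members, camera (limma 3.58.1) was run on the counts with a preset correlation of 0.01, adjusted over the 38 lists tested. Camera with an estimated correlation and fry served as alternatives. Fry tests for a shared direction, and its mixed form (mixed fry) for changes in either direction. Both forms of fry test against no change in any member, whereas camera compares a list with the other genes. The genes named in the text were set by a rule that was also fixed before the data were examined. It takes all members of the m6A writer list, and the 10 largest rises and 10 largest falls among called genes with a mean CPM of at least 5, groups that do not overlap and a symbol that is not a predicted gene. It also takes up to 4 called members of each list with calls and 2 abundant members of each list without, plus Nfkbia, Tnf, Lgr5 and Muc2. Some genes that the rule takes are not reported here. Genes outside the rule, chosen after their values were seen, are Pcna, 4 chromosome 1 copies of mitochondrial DNA and those that the closing observations name as such.

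The test was checked on simulated counts for the same comparison, in 5 draws with 200 changed genes each and 14477 to 14572 genes tested per draw. It called 28.75% of genes changed 2-fold and 76.8% of genes changed 4-fold. The sign was right in 99.4% and 99.8% of these changed genes, called or not. Of 607 calls, 93 (15.3%) fell on unchanged genes, above the nominal share, although 4.72% of unchanged genes had an unadjusted p under 0.05. Camera called all 5 raised lists and 0 of the unchanged lists. The simulated genes were drawn independently, so this cannot check camera on lists whose members vary together. Among the lists that camera called in the data, estimated correlations ran from 0.0644 (cell cycle) to 0.963 (MHC class II). With 30.5% of the real genes at an unadjusted p under 0.05 by edgeR, the shares of calls may also differ from those simulated.

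The alternatives were other scaling factors (relative log expression, library size, upper quartile), DESeq2 1.42.0, limma-voom, legacy or robust options off, no filter, a filter of CPM 1 in 2 libraries, a test against a fold of 1.5, omission of mitochondrial and the 10 most abundant genes, and omission of each library in turn. For lists, genes shared with another list were also left out. After the data were seen, 3 more were added, namely sex as a covariate, omission of markers of other cell types, and factors from nuclear protein-coding genes. Annotation and tables were handled in Python 3.11.15 with pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.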

Results

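Gene expression was measured by RNA sequencing in primary epithelial cells of the mouse colon, in 2 WT and 2 Mettl14 KO libraries. Mettl14 encodes a subunit of the complex that methylates adenosines in mRNA (m6A). Total counts were 22136440 (WT replicate 1), 24991060 (WT replicate 2), 22730188 (KO replicate 1) and 22780451 (KO replicate 2). Transcripts of the mitochondrial genome took 33.8%, 28.8%, 32.7% and 28.6% of the counts in that order. Another 11.1%, 9.52%, 11.2% and 9.97% fell on Gm28661, Gm28437, Gm29216 and Gm10925, chromosome 1 copies of mitochondrial DNA whose reads cannot be told from it. Haemoglobin transcripts made up 0.183%, 0.256%, 0.132% and 0.739%, highest in KO replicate 2.

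The first principal component of log2 CPM held 63.35% of the variance and separated the genotypes, with scores of -50.9 and -22.1 in WT and 37.2 and 35.8 in KO. The next held 25.41% and placed the male libraries (WT replicate 1 and KO replicate 2, both at 22.6) apart from the female ones (-34.0 for WT replicate 2 and -11.1 for KO replicate 1). Across genes, log2 CPM correlated at r = 0.972 between the WT libraries and 0.982 between the KO libraries, against 0.942 to 0.968 between genotypes.

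**Figure D1:**
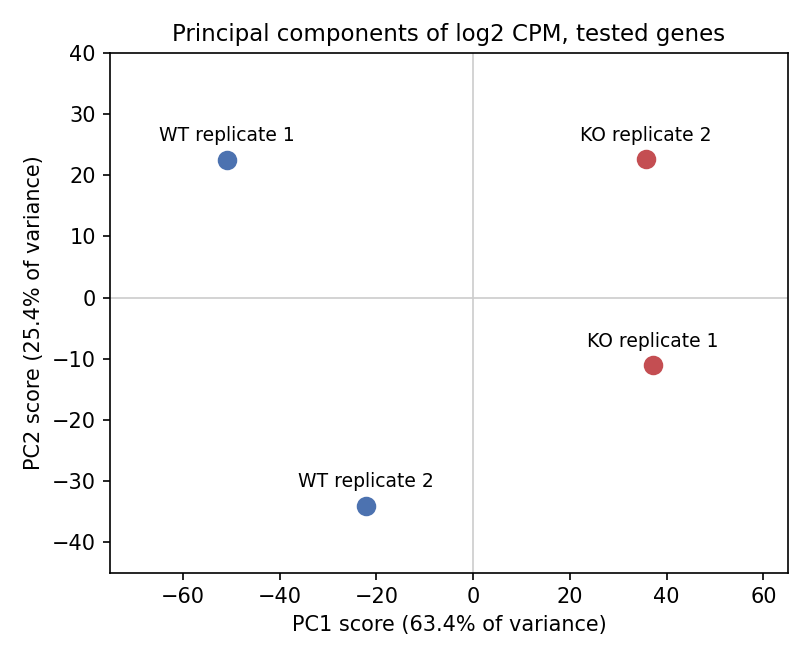
Principal component scores of log2 CPM over the 14861 tested genes, PC1 on the x axis and PC2 on the y axis, 1 point per library (blue WT, red KO). The WT libraries lie at -50.9 and -22.1 on PC1 and the KO libraries at 37.2 and 35.8.

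The design compared KO with WT cells to ask which transcripts differ when Mettl14 is deleted. Mettl14 itself (ENSMUSG00000028114, chromosome 3, 123368297 to 123386108) had 242 and 206 counts (11.7 and 8.67 CPM) in the WT libraries and fewer in KO, with 90 counts (3.99 CPM) in replicate 1 and 3.94 CPM in replicate 2. Its level was 10.2 ± 2.11 CPM in WT and 3.96 ± 0.0386 CPM in KO (SD, n = 2), a log2 fold change of -1.36 (SE 0.22). The edgeR adjusted p was 0.0503 over all genes, just outside the threshold, and the gene passed when adjusted over the list alone. Reads can remain from exons outside the deleted part. Mettl3, the catalytic partner, was at 9.75 ± 1.88 CPM in WT and 5.13 ± 0.526 in KO (log2 fold change -0.93, edgeR adjusted p = 0.0751). Rbm15 was at 13.3 ± 2.09 and 24.1 ± 0.594 CPM (0.85, edgeR adjusted p = 0.0546). The other writer genes had log2 fold changes of 0.35 (1110037F02Rik, also called Virma), 0.42 (Cbll1), 0.11 (Wtap), 0.08 (Rbm15b) and 0.03 (Zc3h13). No writer gene of the 8 was called over all genes, and 1 higher and 2 lower were called when adjusted over the list alone. Over all genes with sex as a covariate, 1 was higher (Rbm15) and 1 lower (Mettl14). Rbm15 gained a call in 7 of 18 alternatives and Mettl3 in 3. Among 14 m6A readers and erasers, Ythdf1 rose from 30.4 ± 0.296 to 55.1 ± 2.22 CPM (log2 fold change 0.86) and Ythdf2 from 26.8 ± 5.41 to 62.4 ± 2.23 CPM (1.22), and 12 were not called. Both encode proteins that bind m6A in mRNA, and the count was also 2 when adjusted over the list alone.

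Over all genes, 255 were higher and 282 lower in KO by edgeR at an adjusted p under 0.05, and 187 and 147 of these changed more than 2-fold. All adjusted p of these calls lay between 0.0434 and the threshold, and 30.5% of the genes had an unadjusted p under 0.05 (2203 higher, 2329 lower). The edgeR adjusted p was under 0.1 for 2682 genes. The threshold thus cut through many genes of similar adjusted p, and a gene just outside it differed little from a called one. Without KO replicate 1 or without KO replicate 2, edgeR called 0 genes, with 2257 and 1987 at an unadjusted p under 0.05, and without WT replicate 2 it called 1271 higher and 1019 lower. With sex as a covariate, a fit chosen after the data were seen, it called 696 higher and 713 lower. That fit leaves fewer residual degrees of freedom. Its sex term sets WT replicate 1 and KO replicate 2 against the other libraries, so it also takes up any other difference between them. DESeq2 called 893 higher and 881 lower, and library size scaling 604 higher and 186 lower, 76.5% higher against 47.5% with TMM.

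Among the genes reported here that were called and had a mean CPM of at least 5, the largest rise was in Muc6, a gel-forming mucin of the stomach (ENSMUSG00000048191, chromosome 7, 141633456 to 141655319), from 0.625 ± 0.544 to 11.8 ± 2.53 CPM (log2 fold change 4.20, SE 0.61). Extl1, a glycosyltransferase of the exostosin family, rose from 2.17 ± 0.619 to 23.3 ± 1.77 CPM (3.42). Stx11 rose from 1.27 ± 0.228 to 11.7 ± 0.0732 CPM (3.20). Far2, which reduces fatty acyl-CoA to fatty alcohols, rose from 3.53 ± 0.362 to 26.5 ± 1.04 CPM (2.91), and the fatty acid binding protein gene Fabp5 from 6.63 ± 2.77 to 44.7 ± 2.85 CPM (2.75). Other large rises were in Plekhs1 (2.94), Trabd2b (2.49), Arhgef10 (2.46) and Tnfaip8l1 (2.33). Among the large falls, Cnpy1 (ENSMUSG00000044681, chromosome 5, 28200819 to 28245806) went from 14.2 ± 4.02 to 2.53 ± 1.0 CPM (log2 fold change -2.48, SE 0.37). The cytochrome P450 genes Cyp2s1 and Cyp2c68 fell from 241 ± 35.5 to 43.7 ± 15.9 CPM (-2.47) and from 39.4 ± 10.7 to 8.75 ± 2.34 CPM (-2.17). Trdmt1, an RNA cytosine methyltransferase, fell from 18.2 ± 6.1 to 4.38 ± 0.921 CPM (-2.06), and Nr1i3, the nuclear receptor CAR, from 12.5 ± 0.0788 to 3.32 ± 0.567 CPM (-1.91). Hoxd10 (-2.06), Fhl1 (-1.82), Ppp1r3b (-1.76) and Il15 (-1.76) were also among the large falls.

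**Figure D2:**
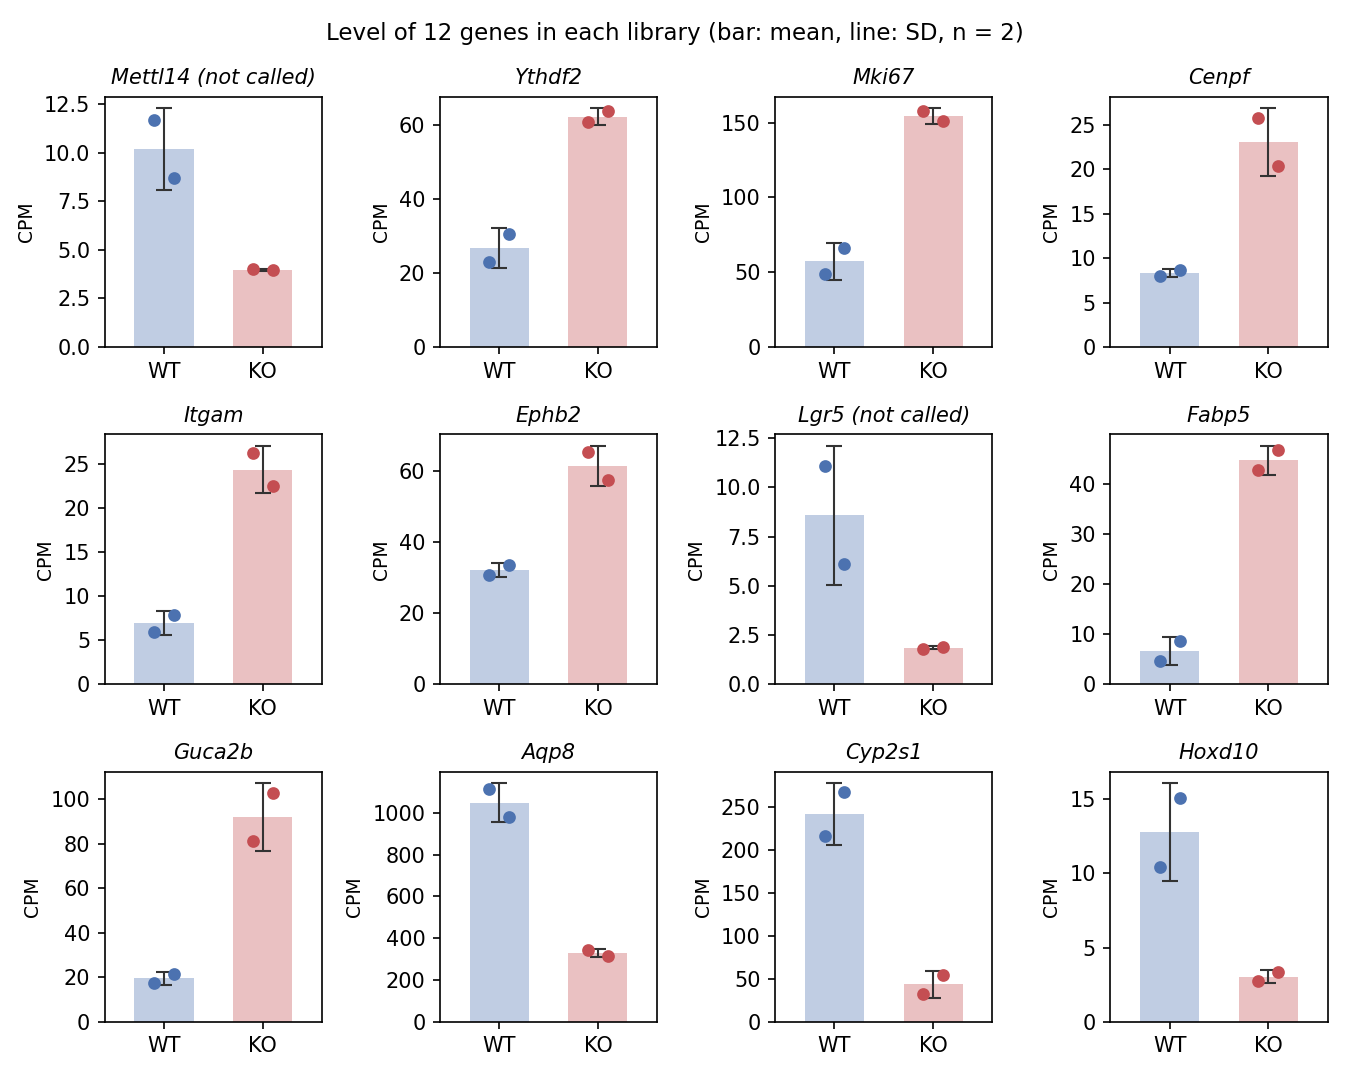
CPM of 12 genes in each library, with dots for libraries, bars for group means and lines for the SD (n = 2); the y axes start at 0 and differ between panels. Mki67 was at 57.2 CPM in WT and 155 in KO, Aqp8 at 1047 and 330.3, and Mettl14 at 10.2 and 3.96.

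Cell cycle genes were higher in KO (camera adjusted p = 1.67e-10, adjusted p = 0.878 with an estimated correlation). Of 25 tested, 6 rose and none fell over all genes, and 23 rose and 1 fell when adjusted over the list alone. Over all genes with sex as a covariate, 11 rose and 1 fell. The proliferation marker Mki67 rose from 57.2 ± 12.3 to 155 ± 5.11 CPM (log2 fold change 1.43), and the mitotic genes Cenpf, Tpx2 and Ccna2 by 1.46, 1.22 and 0.97. Birc5, a mitotic inhibitor of apoptosis protein, rose by 1.11. Pcna, which encodes the sliding clamp of DNA replication and was chosen after its values were seen, went the other way and was the 1 member that fell when adjusted over the list alone (-0.72). The list was higher in both KO libraries than in both WT libraries, at mean log2 CPM of 0.41 and 0.34 against -0.42 and -0.33 relative to the mean of all libraries.

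Colonic stem cell genes were higher as a list (camera adjusted p = 0.0411, adjusted p = 0.878 with an estimated correlation), and this call ended without WT replicate 2, without KO replicate 2 and with library size scaling. The genotypes overlapped. The list stood at 0.03 in WT replicate 1, -0.29 in WT replicate 2, -0.0009 in KO replicate 1 and 0.26 in KO replicate 2 (mean log2 CPM relative to all libraries). Of 18 tested, 2 rose, namely Ephb2 from 32.3 ± 1.91 to 61.5 ± 5.67 CPM (log2 fold change 0.93) and Cd44 from 13.4 ± 1.1 to 29.7 ± 3.47 CPM (1.15), and 5 rose and 1 fell when adjusted over the list alone (5 and 1 also over all genes with sex as a covariate). Lgr5, the marker of crypt base stem cells, was 1 of 5 members with a negative log2 fold change, at 8.59 ± 3.52 CPM in WT and 1.86 ± 0.0648 in KO (-2.20, edgeR adjusted p = 0.0506), and gained a call in 8 of 18 alternatives. Among 16 Wnt targets, Ccnd1 rose from 29.4 ± 1.48 to 59.1 ± 1.9 CPM (1.01), and 2 rose and 1 fell when adjusted over the list alone; the list was not called (camera adjusted p = 0.357).

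Macrophage and monocyte markers were higher in KO (camera adjusted p = 3.12e-07, adjusted p = 0.878 with an estimated correlation). Of 14 tested, 3 rose over all genes (9 with sex as a covariate) and 10 did when adjusted over the list alone. The 3 were the integrin Itgam, from 6.94 ± 1.37 to 24.4 ± 2.69 CPM (log2 fold change 1.81), the chemokine receptor Cx3cr1, from 5.25 ± 0.279 to 13.1 ± 1.06 CPM (1.32), and the complement gene C1qa, from 5.44 ± 0.0746 to 11.6 ± 0.995 CPM (1.09). MHC class II genes were higher as a list (camera adjusted p = 0.00176, adjusted p = 0.878 with an estimated correlation). None of the 8 was called over all genes (5 rose with sex as a covariate) and 6 were when adjusted over the list alone, with Cd74 at 134 ± 60.7 CPM in WT and 295 ± 23.1 in KO and H2-Aa at 64.2 ± 24.6 and 128 ± 14.9. The list stood lowest in WT replicate 1, at -0.92 against -0.05 in WT replicate 2 and 0.64 and 0.33 in KO (mean log2 CPM relative to all libraries). Its median log2 fold change was 0.99, and it was 0.65 with none called without WT replicate 1 and 1.51 with all 8 called without WT replicate 2.

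NF-kB targets were higher as a list (camera adjusted p = 9.72e-04, adjusted p = 0.878 with an estimated correlation), with none of 29 called over all genes and 0 when adjusted over the list alone. With sex as a covariate 4 rose, and DESeq2 called 6 higher. Of 30 tested without 1 WT library, 7 rose without replicate 1 and 12 without replicate 2. Nfkbia, the inhibitor that NF-kB induces, was at 75.8 ± 46.6 CPM in WT and 184 ± 3.92 in KO, Tnfaip3 at 134 ± 97.6 and 226 ± 34.9, and Tnf at 11.1 ± 11.7 and 34.4 ± 2.23. The list stood at -1.13 in WT replicate 1, 0.13 in WT replicate 2, 0.71 in KO replicate 1 and 0.30 in KO replicate 2 (mean log2 CPM relative to all libraries). Neutrophil markers stood at -1.22, 0.22, 1.21 and -0.21 in the same order. All 10 of them had a positive log2 fold change (median 1.29), without a call as a list (camera adjusted p = 0.132), and 3 of the 10 are also members of the NF-kB, cytokine or antimicrobial lists. That list was called with sex as a covariate, without a filter, without WT replicate 2 and without KO replicate 2, and its median was 0.05 without KO replicate 1. Cytokines and chemokines were called as a list (camera adjusted p = 0.0294, adjusted p = 0.878 with an estimated correlation), with 0 of 20 called over all genes (5 rose with sex as a covariate) and 0 when adjusted over the list alone. This call ended without WT replicate 1, without KO replicate 1, with upper quartile factors, with DESeq2, with fry and without genes shared between lists. The median log2 fold change of 0.96 became 0.44 without WT replicate 1, 2.50 without WT replicate 2 and 0.27 without KO replicate 1. Il1b was at 18.6 ± 18.3 CPM in WT and 49.7 ± 40.5 in KO, and Ccl28 at 63.3 ± 13.0 and 50.2 ± 0.236. In the antimicrobial and mucosal defence list (camera adjusted p = 0.0427, adjusted p = 0.878 with an estimated correlation), the acute phase gene Saa3 rose from 6.38 ± 0.578 to 29.6 ± 5.16 CPM (log2 fold change 2.21), the 1 call of 18 over all genes (5 rose with sex as a covariate) and when adjusted over the list alone. The call of that list ended under 12 of 18 alternatives. In 1 more, without WT replicate 1, camera's direction was lower and the list was not called. Its median of 0.89 became 0.28 without WT replicate 1, 1.73 without WT replicate 2 and 0.13 without KO replicate 1.

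Immediate early and heat shock genes were lower as a list (camera adjusted p = 0.00757, adjusted p = 0.878 with an estimated correlation). Of 17 tested, 2 fell over all genes and when adjusted over the list alone, the antiproliferative Btg2 from 517 ± 84.9 to 225 ± 4.08 CPM (log2 fold change -1.20) and the phosphatase Dusp1 from 564 ± 103 to 217 ± 37.9 CPM (-1.38). Posterior Hox genes, which mark the distal colon, were lower (camera adjusted p = 0.0214, adjusted p = 0.878 with an estimated correlation), with 1 of 7 called over all genes and when adjusted over the list alone, Hoxd10, from 12.7 ± 3.29 to 3.05 ± 0.426 CPM (-2.06). Tight junction and adhesion genes were lower (camera adjusted p = 0.0234, adjusted p = 0.878 with an estimated correlation). Of 21 tested, the tight junction gene Marveld3 fell from 59.9 ± 6.71 to 32.8 ± 0.204 CPM (-0.87), and 1 rose and 6 fell when adjusted over the list alone. These 3 list calls ended without WT replicate 2. The median log2 fold change then went from -0.40 to -0.23 for immediate early and heat shock genes (-0.66 without WT replicate 1). For Hox genes it went from -0.79 to -0.37, against -1.11 with 4 of 7 called without WT replicate 1; they stood at 0.66 in WT replicate 2, 0.10 in WT replicate 1 and -0.42 and -0.33 in KO. For tight junction and adhesion genes it went from -0.42 to -0.25 both without WT replicate 1 and without WT replicate 2, with 5 called lower each time. With sex as a covariate 4 immediate early and heat shock genes and 5 tight junction and adhesion genes fell.

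**Figure D3:**
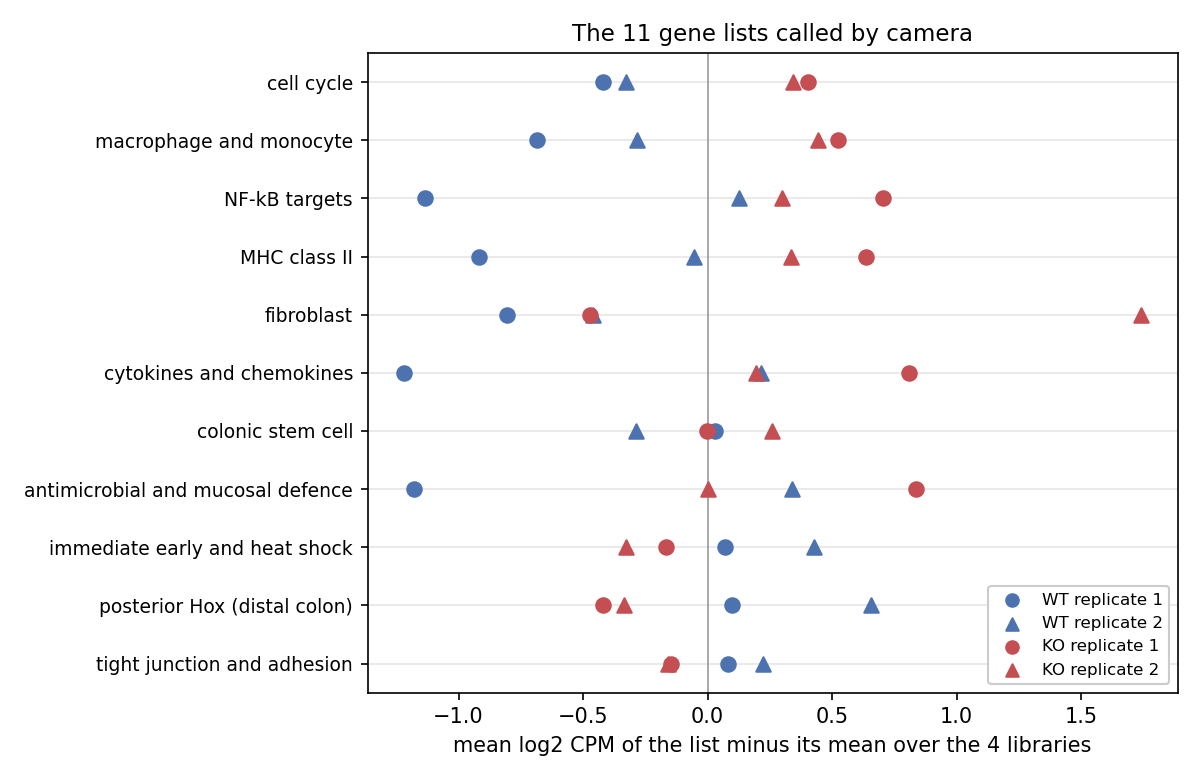
The 11 lists called by camera with a preset correlation, with each library's mean log2 CPM over the list minus its mean over the 4 libraries on the x axis (blue WT, red KO; circles replicate 1, triangles replicate 2). Cell cycle genes lay at -0.42 and -0.33 in WT and 0.41 and 0.34 in KO, while fibroblast genes stood out in KO replicate 2 (1.74).

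Camera did not call the lists of differentiated epithelial cells over the 4 libraries, though single members were called. Mixed fry, which tests for changes in either direction, gave adjusted p of 0.00309 for goblet cell genes, 0.00309 for absorptive colonocyte genes and 0.0124 for tuft cell genes. Its adjusted p was over 0.05 for the enteroendocrine, Paneth cell, small intestinal and Notch lists. Of the lists that camera called, mixed fry gave 0.0316 for cell cycle, 0.0124 for stem cell, 0.0419 for macrophage and 0.0422 for tight junction genes. It gave 0.0974 (antimicrobial) to 0.324 (fibroblast) for the NF-kB, MHC class II, cytokine, antimicrobial, immediate early, Hox and fibroblast lists. Mixed fry does not compare a list with other genes, so a low value does not by itself set a list apart. By camera, the small intestinal list became called higher without WT replicate 1, without KO replicate 2 and with sex as a covariate, and the goblet cell list lower without KO replicate 1. The median log2 fold change of the small intestinal list was 0.27, and 0.84 without WT replicate 1, where 10 of 11 members were positive and 2 called. Of 27 absorptive colonocyte genes, Guca2b, which encodes uroguanylin, rose from 19.5 ± 2.81 to 91.8 ± 15.2 CPM (log2 fold change 2.23). The water channel gene Aqp8 fell from 1047 ± 93.4 to 330.3 ± 20.3 CPM (-1.67); 2 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.486). The absorptive counts over all genes became 2 higher and 5 lower with sex as a covariate, 3 and 5 without WT replicate 1 and 4 and 6 without WT replicate 2. Of 23 goblet cell genes, Bcas1 fell from 75.2 ± 9.5 to 41.8 ± 1.34 CPM (-0.85), and 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.214); sex as a covariate gave 1 higher and 2 lower over all genes. The mucin gene Muc2 was at 1663 ± 7.36 CPM in WT and 1371 ± 0.355 in KO (-0.28, edgeR adjusted p = 0.289). No call over all genes was made among 18 enteroendocrine genes (Chga -0.97, Chgb -0.57), 10 tuft cell genes (Alox5ap 1.11, Hpgds -0.66), 5 Paneth cell genes (Nupr1 0.12, Ang4 -0.72), 10 small intestinal genes (Cubn -0.97, Alpi -0.46) or 11 Notch pathway genes (Rbpj 0.55, Hes1 -0.42). Some of these values rest on WT replicate 1, without which Chga was at -0.19, Chgb at 0.23, Cubn at 0.82 and Alpi at 0.77. Adjusted over the list alone, these gave 1, 0, 0, 1 and 3 higher and 0, 1, 0, 0 and 1 lower. At an unadjusted p under 0.05 by edgeR, 2, 3, 0, 3 and 5 were higher and 1, 2, 0, 0 and 1 lower. Over all genes with sex as a covariate, 1, 1, 0, 2 and 1 were higher and 1 tuft cell gene lower, and DESeq2 called 2, 1, 0, 4 and 1 higher and 1 tuft cell gene lower.

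Camera called none of the following death and stress lists over the 4 libraries. Fadd, an adaptor of death receptors, rose from 11.4 ± 1.37 to 23.2 ± 0.701 CPM (log2 fold change 1.03), the 1 call among 23 apoptosis-promoting genes, and Birc5 was the 1 call among 12 apoptosis-opposing genes; both counts were the same when adjusted over the list alone. Of 23 p53 targets, the exonuclease gene Aen rose from 8.2 ± 0.0524 to 17.2 ± 1.57 CPM (1.07), Trp53inp1 fell from 125 ± 12.4 to 60.7 ± 6.12 CPM (-1.04) and Btg2 fell; 5 rose and 5 fell when adjusted over the list alone. In the unfolded protein and integrated stress response list of 24, the amino acid synthesis genes Asns (0.95) and Phgdh (1.28) and the protein disulfide isomerase gene Pdia4 (1.23) rose, with 3 higher and 1 lower when adjusted over the list alone. Camera adjusted p were 0.998, 0.567, 0.998 and 0.313. Mixed fry, which tests for changes in either direction, gave adjusted p of 0.00369, 0.0845, 0.013 and 0.0254 in the same order. It gave 0.0422 for the oxidative phosphorylation genes described next, and over 0.05 for the other lists described with them. Mixed fry does not compare a list with other genes, and 30.5% of all genes had an unadjusted p under 0.05 by edgeR. The oxidative phosphorylation genes passed with 4 of 20 at that level, below that share. A low mixed fry value therefore does not by itself set a list apart. The 18 necroptosis and pyroptosis genes (Gsdmd 0.04, Gsdmc4 -0.33), 38 interferon response genes (Irf7 -0.12, Ifit1bl1 0.27), 15 regenerative genes (Ly6a 0.80, Anxa8 -0.99), 23 cholesterol biosynthesis genes (Hmgcs1 0.19), 18 fatty acid oxidation genes and 20 oxidative phosphorylation genes (Atp5a1 0.02, Atp5b -0.23) gave 0 calls over all genes and 0 when adjusted over the list alone by edgeR, with 1, 1, 4, 6, 4 and 4 at an unadjusted p under 0.05. With sex as a covariate, 2 necroptosis and pyroptosis genes were higher and 1 lower, 3 regenerative and 2 fatty acid oxidation genes were lower, and the other 3 lists again had 0 calls. DESeq2 called 0, 1, 1, 1, 0 and 1 higher and 1, 0, 2, 1, 2 and 0 lower, and limma-voom 0. Several of these counts rest on 1 library. Without WT replicate 2, 7 interferon response genes (median 0.73, against 0.02 over the 4 libraries) and 9 cholesterol biosynthesis genes (0.55, against 0.20) were called higher, and 4 fatty acid oxidation genes lower. Without WT replicate 1 these medians were -0.30 for interferon response, with 29 of 38 negative, and -0.02 for cholesterol biosynthesis. By camera, both lists were called higher without WT replicate 2, and the interferon list also without KO replicate 2. The list median, mean and camera direction differed in sign for apoptosis-promoting genes, p53 targets, regenerative genes, enteroendocrine genes and m6A writers.

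Markers of other cell types were examined too. Fibroblast genes were higher as a list (camera adjusted p = 0.00556, adjusted p = 0.878 with an estimated correlation), with none of 13 called over all genes and 1 when adjusted over the list alone. Their summed CPM was 99.0 and 134 in WT and 130 and 736 in KO, so that KO replicate 2 alone was high, and the call ended without it. Col3a1 was at 33.0 ± 8.28 CPM in WT and 171 ± 194 in KO, and Col1a2 at 13.8 ± 5.07 and 55.4 ± 62.5, with a log2 fold change of -0.28 for Col1a2 without KO replicate 2. The erythroid genes were also highest in KO replicate 2, at a summed CPM of 6681 against 1353 to 2736 elsewhere (Hbb-bs 0.80, Hba-a2 0.72, and -0.75 and -0.80 without that library). By edgeR, 0 genes were called among 14 T cell markers (Ptprc 0.15, Itgae 0.34), 10 B and plasma cell markers (Ighm 0.39, Cd79b 0.07), 10 neutrophil markers (Ly6g 0.09, Il1b 1.41), 7 smooth muscle markers (Acta2 1.28, Tagln 0.50) and 5 enteric neuron and glia markers (Ret 0.03, Snap25 -0.96). The same held when adjusted over the list alone, with 1, 1, 0, 2 and 1 at an unadjusted p under 0.05. With sex as a covariate 1 T cell marker and 2 neutrophil markers were higher, and DESeq2 called 1 T cell and 1 smooth muscle marker higher. Median log2 fold changes were 1.97 for fibroblast (-0.10 without KO replicate 2), 1.29 for neutrophil, 0.90 for smooth muscle (0.19 without KO replicate 2), 0.80 for erythroid, 0.21 for B and plasma cell and 0.19 for T cell markers, against 1.10 for macrophage and monocyte markers. The B and plasma cell median was 1.22 without WT replicate 2, where camera called the list higher, and -0.32 without WT replicate 1, and the smooth muscle list was called higher without KO replicate 1. Endothelial markers had 3 tested members (Vwf 1.92, Pecam1 0.60) and no list test. Xist (-0.40) and Kdm5d (-0.31), from which sex was read, were each high in 1 library per group.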

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

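The labels pair no libraries, and the fit with sex as a covariate was the only one with a term besides genotype. Sex as a covariate, omission of other cell types' markers and nuclear factors were chosen after the data were seen. The counts of genes higher and lower (255 and 282) stayed within 1.5 times under relative log expression (217, 219), robust off (243, 263), legacy off (275, 302), limma-voom (282, 300), the stricter filter (366, 388), omission of mitochondrial and abundant genes (292, 254), omission of other cell types' markers (298, 323) and nuclear factors (295, 273). They became 604 and 186 with library size, which shifted the median log2 fold change of all genes by 0.17, 416 and 265 with upper quartile factors, 862 and 770 without a filter, 696 and 713 with sex as a covariate and 893 and 881 with DESeq2, where all 537 calls were kept. Against a fold of 1.5, edgeR called 0 and 0 (956 and 701 at an unadjusted p under 0.05). Leaving out each library gave 0 to 1271 higher and 0 to 1019 lower; 1 library is then assumed to vary like the other group. All 537 called genes kept their sign without any 1 library. This was nearly fixed in advance, as they were chosen by the fit to all libraries, so it gives no separate support.

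Mettl14 passed the threshold with library size (-1.19), legacy off (-1.357), no filter (-1.329), the stricter filter (-1.35), sex as a covariate (-1.344), omission of other cell types' markers (-1.355) and DESeq2 (-1.345), with adjusted p of 0.0017 to 0.05 by those edgeR and DESeq2 fits, and without either WT library. Without each library its log2 fold change ran from -1.523 to -1.138. Of 8 lists higher and 3 lower, camera with an estimated correlation and fry for a shared direction called 0 and 0. The adjusted p of 0.878 by that camera was the same for each of them, but unadjusted p differed. It was 0.0402 for cell cycle genes, 0.083 for macrophage markers and 0.266 to 0.493 for the rest. By fry for a shared direction, unadjusted p was 0.00326, 0.0249 and 0.0624 to 0.357 in the same order. By camera with the preset correlation, 5 lists were higher when other cell types' lists were left out. Leaving out each library gave 7 to 12 lists higher and 0 to 4 lower. Cell cycle, macrophage, NF-kB and MHC class II genes kept their calls under the other alternatives in which they were tested; the macrophage list was not tested when other cell types' lists were left out. The direction of Alpi (-1.083 to 0.773) turned without WT replicate 1, where it was called higher, and it was called lower without WT replicate 2. Also turned were the antimicrobial list without WT replicate 1 (signed adjusted p from -0.963 to 0.3851), the regenerative list without WT replicate 2 or KO replicate 2 (-0.5185 to 0.5011) and the erythroid list without KO replicate 2 (-0.0156 to 0.7951). By camera, the regenerative list was called higher without WT replicate 2 (adjusted p = 0.0462), and the erythroid list higher without KO replicate 1 (adjusted p = 2.64e-07) and lower without KO replicate 2. Other uncalled genes also changed sign without WT replicate 1, among them Chgb, Cubn, Ly6a, Ly6g and Gsdmd. The cause was not tested for any of these. Depth limits genes under about 0.14 CPM, the level a count of 0 allows.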

Other observations

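The tests on single-exon genes, on mitochondrial mRNAs, on the epithelial share and on WT replicate 1 were chosen after the result was seen. Those on GC content, length and level, on genomic DNA and on RNA without a poly(A) tail were set before their values were seen. Genes named below lie outside the naming rule and were chosen after their values were seen.

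Among called genes outside the fixed lists, the ferritin turnover receptor gene Ncoa4 fell from 540 ± 14.7 to 201 ± 45.0 CPM (log2 fold change -1.43), and the iron exporter gene Slc40a1 from 1350 ± 130 to 559 ± 73.2 CPM (-1.27). The mitophagy receptor gene Bnip3 fell from 160 ± 44.2 to 53.7 ± 6.69 CPM (-1.57), and the mitochondrial kinase gene Pink1 from 104.6 ± 5.29 to 54.3 ± 2.28 CPM (-0.94). These are single genes, and no list or enrichment that holds them was tested. As for every call, edgeR made 0 calls without KO replicate 1 or without KO replicate 2.

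The mitochondrial rRNA genes mt-Rnr1 and mt-Rnr2 fell from 6978 ± 176 to 2197 ± 570 CPM (log2 fold change -1.67) and from 12840 ± 129 to 3945 ± 450 CPM (-1.70). Less mitochondrial RNA as a whole was argued against, since the 13 mitochondrial mRNAs had a median log2 fold change of 0.090, from -0.35 to 0.75. A lower carry-over of RNA without a poly(A) tail would lower histone and small non-coding RNAs too; the 26 tested had a median of -0.70, short of the -0.8 set beforehand but at -0.85 without KO replicate 2 and -0.44 without WT replicate 2, and 19 of 21 histone genes were negative. This explanation may hold and stays open, because Rn7sk was at 0.81, many of these genes have few counts and only 1 histone gene was called (lower). Whether the histone reads came from transcripts without a poly(A) tail was not measured. Rn7s1 and Rn7s2 had identical values in every library, so they are not separate observations. An effect of genotype on rRNA levels stays open as untested.

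Macrophage markers and NF-kB targets were higher in KO as lists. A lower epithelial share of the KO preparations could raise macrophage markers. If it raised all other cell types alike, T cell markers would rise as much. The macrophage median log2 fold change exceeded that of the T cell markers by 0.91, with quartiles of 0.74 to 1.21 and -0.06 to 0.31. This argues only against an equal rise of all other cell types as the whole cause. It cannot decide on a carry-over that favours some cell types, because T cell markers need not follow it. Neutrophil markers had a median of 1.29 (0.05 without KO replicate 1), near or above that of the macrophage markers. So did fibroblast markers (1.97, but -0.10 without KO replicate 2) and smooth muscle markers (0.90, but 0.19 without KO replicate 2). A lower epithelial share with a rise of several other cell types therefore stays open. WT replicate 1 alone did not carry the macrophage markers, whose median was 0.86 without it (camera adjusted p = 3.89e-05). NF-kB targets kept their camera call without WT replicate 1 (adjusted p = 8.98e-04) and 7 of 30 were called higher by edgeR, but their median went from 0.84 to 0.38, between the bounds of 0.2 and 0.5, so how much of it WT replicate 1 and how much genotype gives cannot be told apart with WT replicate 2 as the only WT library. More macrophages in the KO preparations, or higher expression per cell, may account for the macrophage markers, and neither was tested.

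Because m6A is known to be sparse near exon junctions, its loss may raise transcripts with few junctions most; m6A was not measured here. In the extreme case, the median log2 fold change of 261 single-exon genes exceeded that of multi-exon genes by 0.052 (0.013 to 0.184 without each library), with 10 called higher and 5 lower by edgeR and 56 and 32 at an unadjusted p under 0.05; camera gave p = 0.181 (0.431 with an estimated correlation), which leaves it undecided. Among 13273 multi-exon protein-coding genes, log2 fold change fell weakly with junctions per kb (Spearman rho -0.079 across genes, which are not independent replicates; -0.07 to -0.09 without each library), and the fifth of genes with fewest junctions had 81 higher and 45 lower calls against 25 and 58 in the fifth with most. GC content, length and level did not account for this (partial rho -0.074), nor did genomic DNA in the KO libraries, as olfactory receptor genes had a log2 ratio of -0.33. Over all tested genes, log2 fold change fell more strongly with mean CPM (Spearman rho -0.19), a trend whose cause was not tested. The bound for the junction gradient was set after its rho was seen, so it gives the hypothesis no separate test. Whether loss of m6A accounts for the junction gradient stays open.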
